A study of Mus musculus with 23 samples.

How the data were processed

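Microglial RNA from the mouse striatum was sequenced as 23 libraries, 8 of the Saline group, 8 of the Maintenance group and 7 of the Abstinence group, made with a kit for low RNA input, per the labels' protocols. Per the submitters' processing notes, Trim Galore 0.6.7, cutadapt 1.18, STAR 2.7.10a, StringTie 2.1.5 and DESeq2 1.38.3 were used with the mouse genome build mm10 (GRCm38). The notes give no order or settings, and the labels state neither the strand of the reads nor the hour of isolation of each library. Both deposited tables hold counts of reads per gene as whole numbers, per the file headers and values, with genes named by symbol. The first covers 35976 genes in all 23 libraries and was used for every result. The second is called normalized but held the same deposited counts in 17 of the libraries (5 Saline, 5 Maintenance, 7 Abstinence): 0 of 611592 values differed. It served to choose 1 alternative set of libraries.

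Of the 35976 symbols, 32501 matched a RefSeq gene of GRCm38.p6, from which positions were taken. Of 994 entries in 41 gene lists, 974 matched the table directly, 13 through a synonym and 7 were absent. Overlapping genes cannot be told apart without strand. This was checked for 45 genes with a position that were named by p, by class or in advance. A gene with counts overlapped 22 of them and a tested gene 19, and none of these overlapping genes passed in any comparison. Genes named only as list members were not part of this check. Limits that a count of 0 allows (3 counts of the library's total) cover counting error only.

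Genes were kept with edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 16121. Library sizes were scaled with TMM factors, and CPM are TMM-scaled. Log2 CPM for plots and marker means used a prior count of 2. All 23 libraries entered 1 quasi-likelihood fit with group as the only factor (edgeR 4.0.16: estimateDisp, glmQLFit with robust = TRUE, glmQLFTest), with 3 pairwise contrasts and 1 test over all groups. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Genes that moved back passed in Maintenance against Saline and the opposite way in Abstinence against Maintenance. Genes that stayed changed passed the same way in Maintenance and in Abstinence against Saline, and a last class passed the same way in Abstinence against both other groups. The common biological coefficient of variation was 0.831.

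Genes were named by a rule: per contrast, the 12 higher and 12 lower genes of smallest p among those that passed, with mean log2 CPM of at least 2, group medians in the direction of the fit and no predicted or clone symbol; up to 4 members of each list that passed; up to 4 per class and direction; and Tmem119, P2ry12, Cx3cr1, Csf1r, Il1b, Tnf, Apoe, Fkbp5, Per1 and Fos whatever their p. Gene lists covered microglial states, stress responses, metabolism, clock and hormone responses, and markers of other cells that an isolate could hold. Lists with at least 4 tested members were tested with limma's camera (limma 3.58.1) at an inter-gene correlation of 0.01, adjusted over lists, with the correlation estimated from the data and limma's fry as alternatives. Members that passed were counted over all genes tested and adjusted over the list alone. Lists, rule and these tests were fixed in advance.

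Total counts, genes detected, the share of mitochondrially encoded and of the most abundant genes, and mean log2 CPM of 12 marker lists were compared with two-sided exact permutation tests of group means, adjusted over 48 tests. Whether the 12 lists moved apart was tested, after the values were seen, with the mean over lists taken off in each library, lists scaled by their SD and an exact permutation of the summed squared group differences. Correlation of fold changes across genes was set beside 20 simulations of unchanged groups that shared the Saline libraries and 35 splits of the Saline libraries into 2 sets of 4. Genes called with 4 Maintenance libraries were followed in the other 4 in 35 splits, read both ways, a check added after the data were seen. The gene test was tested on simulated data with 200 changed genes: at 1.5-fold, 2-fold and 4-fold it recovered 40.3%, 70.1% and 92.4% for Maintenance against Saline (15207 genes), 35.8%, 79.1% and 93.9% for Abstinence against Saline (15204 genes) and 40.3%, 67.2% and 89.4% for Abstinence against Maintenance (15230 genes). False calls were 4.3%, 5.4% and 3.7% of calls in these comparisons, and 0 genes were called with nothing changed. The changed genes were drawn from those with a mean log2 CPM of at least 2.

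Alternatives planned in advance were RLE and upper-quartile factors, no filter, a filter of 1 CPM in every library of a group, DESeq2 1.42.0, limma voom with quality weights, replicate number as a block, only the compared groups in the fit, robust = FALSE, 1 surrogate variable (sva 3.50.0) and each library left out in turn. Added after the data were seen were the 17 libraries of the second table, with edgeR and with DESeq2, leaving out Maintenance 6 and 7 or 6, 7 and 8, and oligodendrocyte and neutrophil marker means as covariates. Group labels were also redrawn in 100 splits per result. Isoforms and raw reads were not analysed here. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.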

Results

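RNA was sequenced from microglia isolated from the striatum of male C57BL/6J mice that had self-administered saline or methamphetamine through an intravenous catheter. Sessions lasted 2 hr and were held daily for 15 days, with methamphetamine at 0.05 mg/kg per infusion. The Saline group (n = 8 libraries) and the Maintenance group (methamphetamine, n = 8) were collected after the last session, and the Abstinence group (methamphetamine, n = 7) after a further 21 days in the home cage without the drug. The 23 libraries hold no saline group that passed through the 21 days, so the Abstinence libraries differ from the Saline libraries in drug history, age and home cage time together. Counts for 35976 genes totalled 55 to 94.8 M (1e6) per library (median 75.4 M). Mean totals were 70.8 ± 10.2 M in Saline, 76.8 ± 14.2 M in Maintenance and 82.0 ± 9.0 M in Abstinence (SD). The groups had 16279 ± 742, 14958.5 ± 1591 and 16277 ± 737 genes detected in that order. Among the Maintenance libraries, replicates 6 and 7 had the fewest detected genes (12459 and 12740), and replicate 8 carried markers of choroid plexus and ependymal cells at a mean of 6.27 log2 CPM, against -3.23 to 0.29 in the other 7. The labels give the cell type as microglia but the tissue as neuronal. In Saline the microglial gene Tmem119 measured 4210 ± 667 CPM, and striatal neuron markers averaged 1.07 log2 CPM. The labels do not state that each replicate came from a separate animal, so the p-values measure the spread between samples. Below, gene levels are mean CPM (counts per 1e6 counts) ± SD over the 8 Saline, 8 Maintenance and 7 Abstinence libraries, and log2 fold changes are given ± SE from an edgeR fit of 16121 genes.

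The first comparison asked how striatal microglia at the end of methamphetamine taking differed from those of mice that took saline over the same sessions. Chaperone genes rose in the Maintenance group. Hspa8 (chromosome 9, 40801276 to 40805202, GRCm38.p6), which encodes the constitutive Hsp70 protein that folds newly made proteins, rose 1.86-fold from 1866 ± 193 CPM in Saline to 3472 ± 405 CPM in Maintenance (log2 fold change 0.90 ± 0.09, adjusted p = 1.1e-06). Hsph1 (chromosome 5, 149616843 to 149636498), a nucleotide exchange factor of Hsp70, rose 2.61-fold from 33.9 ± 2.37 to 88.5 ± 16.5 CPM (SE 0.16 on the log2 scale, adjusted p = 1.95e-05). The Hsp70 co-chaperone Dnaja1 (chromosome 4, 40722468 to 40734965) rose 1.97-fold from 121 ± 12.5 to 238 ± 22.6 CPM (0.98 ± 0.10, adjusted p = 4.23e-06). Partners of Hsp90 rose as well, with fold changes of 2.7 for Ahsa2, 2.04 for Chordc1, 1.9 for Stip1 and 1.52 for Fkbp4, and adjusted p from 1.37e-06 for Ahsa2 to 0.000612 for Fkbp4. The gene of the constitutive Hsp90 protein, Hsp90ab1, rose from 872 ± 99.6 to 1463 ± 220 CPM (0.75 ± 0.12, adjusted p = 0.00132). Each of these genes lay above the Saline median in 8 of 8 Maintenance libraries. Of the 19 measured heat-shock chaperones fixed as a list, 9 rose over all genes tested and 14 when adjusted over the list alone. Of the same genes 18 had a positive fold change, and the median log2 fold change was 0.77. The list ranked above other genes (camera adjusted p = 1.72e-45; adjusted p = 3.38e-05 with an estimated correlation). The heat-inducible member Hspa1a, whose reads are uncertain because Hspa1b is a near-identical copy, measured 427 ± 108 CPM in Saline and 728 ± 164 CPM in Maintenance (0.77 ± 0.25, adjusted p = 0.154). Outside the list, Eif4a2, an RNA helicase of translation initiation, rose 1.37-fold (adjusted p = 0.000353). Rrbp1, a ribosome-binding protein of the endoplasmic reticulum, rose 1.55-fold (adjusted p = 0.00124), and Tpr, a nuclear pore protein, rose 1.46-fold (adjusted p = 0.00224). Mean oligodendrocyte markers in the same libraries were 6.08 ± 0.83 log2 CPM in Saline and 6.87 ± 0.64 in Maintenance (two-sided exact permutation p = 0.0513, adjusted p = 0.15). Mean neutrophil markers were 2.76 ± 1.47 and 0.71 ± 1.06 (exact permutation p = 0.00653, adjusted p = 0.0656). Mean monocyte markers were 1.96 ± 0.84 and 0.62 ± 0.80 (exact permutation p = 0.00404, adjusted p = 0.0656). Mean lymphocyte markers were 0.42 ± 0.54 in Saline and -0.95 ± 0.78 in Maintenance (exact permutation p = 0.00202, adjusted p = 0.0656). Of the 9 called chaperones, 8 still passed without Maintenance 6, 7 and 8, and 7 passed with both marker means as covariates, settings chosen after the values were seen.

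**Figure D1:**
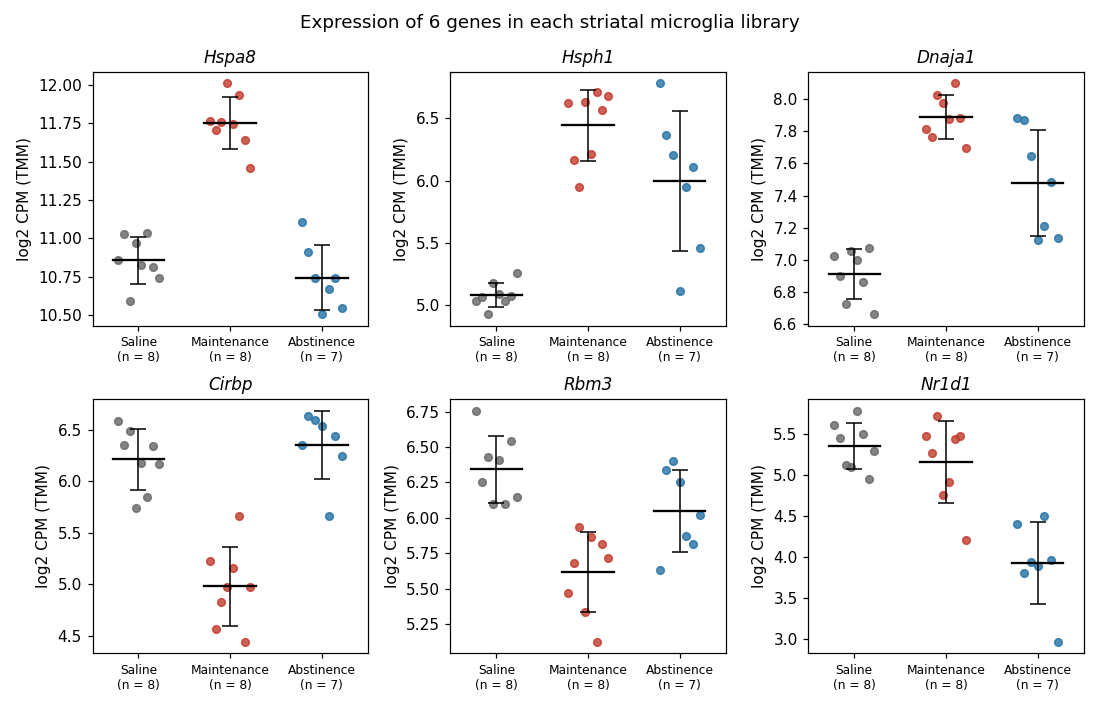
Levels of 6 genes in each library (points, log2 CPM) of the Saline (n = 8), Maintenance (n = 8) and Abstinence (n = 7) groups, with the group mean as a line and the SD as bars. Hspa8 and Cirbp moved in opposite directions in Maintenance (log2 fold changes 0.90 and -1.21) and Nr1d1 fell in Abstinence (-1.39 against Saline).

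Single genes that fell in Maintenance included some of RNA-binding proteins. A list of 46 further splicing regulators, chosen after these genes were seen, went the other way (median log2 fold change 0.15, 5 rose and 1 fell, limma's fry adjusted p = 0.0077). Cirbp (chromosome 10, 80165990 to 80172786), a cold-inducible RNA-binding protein, fell from 75.4 ± 14.7 CPM in Saline to 32.6 ± 9.06 CPM in Maintenance (log2 fold change -1.21 ± 0.16, adjusted p = 7.37e-05). Rbm3 (chromosome X, 8138975 to 8145880), another RNA-binding protein induced by mild cold, fell from 82.0 ± 13.9 to 49.9 ± 9.24 CPM (-0.72 ± 0.13, adjusted p = 0.0047). The RNA-binding protein gene Ewsr1 fell by 0.41 ± 0.07 on the log2 scale (adjusted p = 0.00285). The splicing regulators Srsf5 and Ptbp1 fell by 0.68 ± 0.11 and 0.51 ± 0.09 (adjusted p = 0.00103 and 0.00544). Mthfd2 (chromosome 6, 83305704 to 83326011), a mitochondrial folate enzyme, fell from 26.9 ± 8.15 to 11.9 ± 2.58 CPM (-1.18 ± 0.20, adjusted p = 0.00211). Phgdh, which begins serine synthesis, fell from 162.5 ± 13.3 to 113.5 ± 12.1 CPM (-0.52 ± 0.08, adjusted p = 0.00171), as did the alanyl-tRNA synthetase gene Aars, by 0.35 ± 0.06 (adjusted p = 0.0047). Csf2ra, the GM-CSF receptor alpha chain, fell by 0.61 ± 0.10 (adjusted p = 0.00169), and Csf3r, the G-CSF receptor and also a neutrophil marker, by 0.39 ± 0.07 (adjusted p = 0.00997). Etv5 (chromosome 16, 22381313 to 22439570), an ETS-family transcription factor, fell from 136 ± 22.2 to 87.6 ± 13 CPM (-0.64 ± 0.11, adjusted p = 0.00211). Nubp1, an assembly factor of iron-sulfur proteins, fell from 41.5 ± 6.87 to 22.7 ± 5.58 CPM (-0.87 ± 0.17, adjusted p = 0.00873). All of these genes lay below the Saline median in 8 of 8 Maintenance libraries. With the oligodendrocyte and neutrophil marker means as covariates, added after the values were seen, 6 calls ended with wider errors. The log2 fold changes were then -0.51 ± 0.14 for Etv5 (adjusted p = 0.165), -0.31 ± 0.08 for Aars (0.157), -0.85 ± 0.22 for Nubp1 (0.125), -0.54 ± 0.12 for Ptbp1 (0.0719), -0.71 ± 0.16 for Rbm3 (0.0591) and -0.32 ± 0.09 for Csf3r (0.2), and those of Etv5, Aars and Csf3r were also smaller. In that fit Cirbp, Ewsr1, Srsf5, Mthfd2, Phgdh and Csf2ra passed.

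In all, 114 of 16121 genes changed between Maintenance and Saline by edgeR's quasi-likelihood test (54 higher, 60 lower), and 1900 had an unadjusted p under 0.05. Without Maintenance 6, 7 and 8, 85 genes changed, 56 of them among the 114. The count was 62 without Saline 1, 60 without Saline 2, 42 without Saline 3, 70 without Saline 4 and 197 without Saline 8. Among the 8 called genes with a log2 fold change beyond 2 in size, named here after their values were seen, the choroid plexus gene Enpp2 measured 31100 CPM in Maintenance 8 and its fold change went from 5.44 ± 1.26 (adjusted p = 0.048) to 1.21 ± 0.39 (adjusted p = 0.159) without that library. Cd55 (adjusted p = 0.165) and Ociad2 (adjusted p = 0.157) also failed without Maintenance 8, and Sostdc1 (910 CPM in Maintenance 8) was then too low to be tested. The other 4 of the 8 still passed, among them Fmo2 (adjusted p = 0.0163) and Rgs6 (adjusted p = 0.0329).

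Of the gene lists fixed before the data were examined, 20 differed between Maintenance and Saline, and 1 of these, the chaperones, also passed with an estimated correlation. With limma's fry 4 passed: the chaperones (adjusted p = 1.65e-06), the phagocyte NADPH oxidase and lymphocyte markers (0.00662 each), and actin and motility genes (0.00778). The last list had 38 genes with a median of -0.10 (camera adjusted p = 0.0012; adjusted p = 0.254 with an estimated correlation). All 78 cytosolic ribosomal protein genes had a negative fold change (median log2 fold change -0.26, camera adjusted p = 8.62e-22). Of these Rps2 fell over all genes tested and 38 fell when adjusted over the list alone (adjusted p = 0.324 with an estimated correlation). Rps2 (-0.34 ± 0.08, adjusted p = 0.0329) did not pass without Saline 1 (0.0702), 2 (0.0562), 3 (0.0863), 5 (0.0593), 6 (0.0514) or 7 (0.0567), or Maintenance 2 (0.0615), 6 (0.0512) or 7 (0.0571). The 8 genes of the phagocyte NADPH oxidase, which makes superoxide, were all lower (median -0.23, adjusted p = 0.00166). They had 0 passing over all genes tested and 4 when adjusted over the list alone (adjusted p = 0.173 with an estimated correlation). Its membrane subunit Cyba measured 889.5 ± 87.8 CPM in Saline and 739 ± 124 CPM in Maintenance (adjusted p = 0.203). Chromatin regulators were higher (45 genes, median 0.11, adjusted p = 0.000431; adjusted p = 0.173 with an estimated correlation), with 0 passing over all genes tested and 1 adjusted over the list alone, and with Crebbp at 167.5 ± 11.2 and 205 ± 23.3 CPM (adjusted p = 0.0784). Markers of other cells moved in both directions. The 16 oligodendrocyte markers were higher (median 0.86, adjusted p = 1.45e-10; adjusted p = 0.207 with an estimated correlation). Over all genes tested 0 passed, and 2 when adjusted over the list alone. Neutrophil markers were lower (13 genes, median -1.14, adjusted p = 0.000241; adjusted p = 0.254 with an estimated correlation). Among them Csf3r fell over all genes tested and 3 fell when adjusted over the list alone. Csf3r did not follow the list into Abstinence, where it was at the Saline level (0.03 ± 0.08, edgeR adjusted p = 0.999) while the list median was -1.76. Without Saline 6 the neutrophil list gave adjusted p = 0.0574. The granule gene Mpo measured 22.1 ± 48.0 CPM in Saline, with counts in 7 of 8 libraries, but Saline 5 alone held 139 CPM, and the mean without it was 5.37 ± 8.68 CPM. It had 0 counts in the 15 Maintenance and Abstinence libraries, which by counting error alone allows up to 0.0546 CPM in the shallowest of them. Border macrophage markers were higher (median 0.30, adjusted p = 0.000204; adjusted p = 0.173 with an estimated correlation; 0 passing over all genes tested and 3 adjusted over the list alone). Monocyte (median -0.78, adjusted p = 0.00232) and erythrocyte markers (median -1.02, adjusted p = 0.00202) were lower (both adjusted p = 0.267 with an estimated correlation; 0 passing over all genes tested or adjusted over the list alone). Lymphocyte markers were lower too (10 genes, median -0.22, adjusted p = 0.0292; adjusted p = 0.173 with an estimated correlation; 0 passing either way), but not without Saline 6 (0.0556), Maintenance 1 (0.0654) or Maintenance 8 (0.0752). The oligodendrocyte mean minus the neutrophil mean, a measure chosen after the values were seen, was 3.32 ± 1.93 in Saline, 6.16 ± 1.6 in Maintenance and 6.49 ± 0.9 in Abstinence. No test is given for it, since it was built from lists already seen to move.

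**Figure D2:**
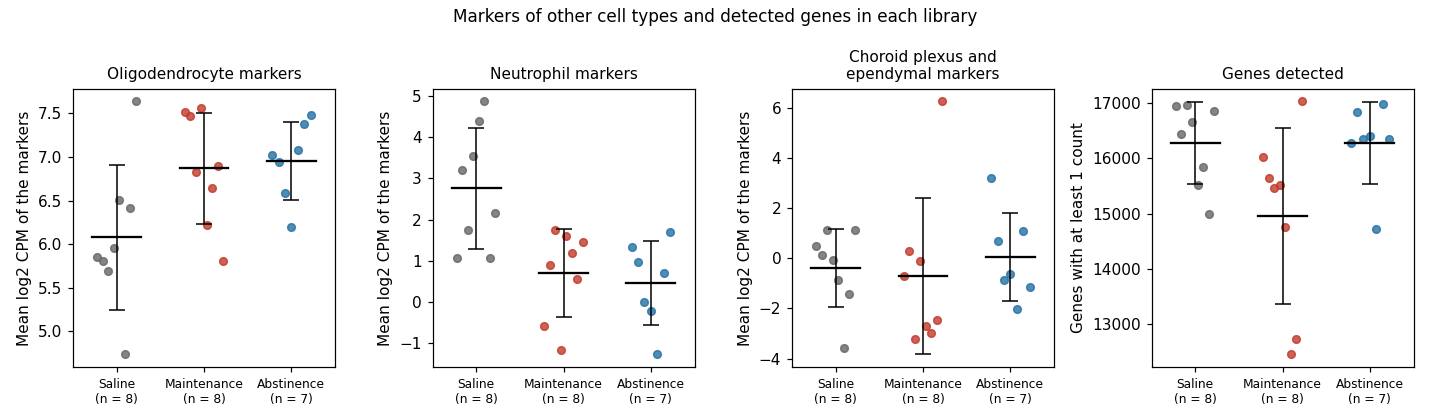
Mean log2 CPM of oligodendrocyte, neutrophil and choroid plexus or ependymal marker genes, and the number of genes detected, per library (points) with the group mean and SD, in Saline (n = 8), Maintenance (n = 8) and Abstinence (n = 7). Neutrophil markers averaged 2.76, 0.71 and 0.46 log2 CPM in the 3 groups, and Maintenance 8 lay apart in choroid plexus markers at 6.27.

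The next comparison asked what remained different from Saline after the 21 days without the drug. The chaperones Hsph1 and Dnaja1 were higher and the clock gene Nr1d1 was lower in Abstinence. Hsph1 rose 2-fold, from 33.9 ± 2.37 CPM in Saline to 67.9 ± 25 CPM in Abstinence (log2 fold change 1.00 ± 0.17, adjusted p = 0.0196), and Dnaja1 rose 1.51-fold, from 121 ± 12.5 to 182 ± 42.1 CPM (0.59 ± 0.11, adjusted p = 0.0433). Nr1d1 (chromosome 11, 98767932 to 98775377), which encodes the circadian repressor Rev-erb alpha, fell from 41.5 ± 8.16 to 15.8 ± 4.88 CPM (-1.39 ± 0.21, adjusted p = 0.00676). Thra overlaps Nr1d1 and was not called (0.51, adjusted p = 0.999). All 3 genes were beyond the Saline median in 7 of 7 Abstinence libraries. The heat-inducible Hspa1a averaged 427 ± 108 CPM in Saline and 1092 ± 513 CPM in Abstinence (1.35 ± 0.25, adjusted p = 0.0824). Its co-chaperone Bag3 averaged 31.0 ± 3.97 and 55.8 ± 18.1 CPM (0.84 ± 0.18, adjusted p = 0.142). Heat-shock chaperones as a list were higher (19 genes, median log2 fold change 0.29, camera adjusted p = 6.59e-15; adjusted p = 0.0195 with an estimated correlation). Of them, 2 rose over all genes tested and 7 when adjusted over the list alone. Circadian clock genes as a list were lower (21 genes, median -0.21, adjusted p = 4.2e-05; adjusted p = 0.0195 with an estimated correlation), with 1 falling over all genes tested and 5 when adjusted over the list alone. Oligodendrocyte markers were again higher (median 0.88, adjusted p = 6.59e-15; adjusted p = 0.16 with an estimated correlation; 0 passing over all genes tested or adjusted over the list alone). Neutrophil markers were lower (median -1.76, adjusted p = 2.55e-08; adjusted p = 0.146 with an estimated correlation; 0 passing over all genes tested and 3 adjusted over the list alone). With both marker means as covariates, 0 genes passed by edgeR, and the estimates were 0.97 ± 0.23 for Hsph1 (adjusted p = 0.854), 0.65 ± 0.15 for Dnaja1 (adjusted p = 0.707) and -1.41 ± 0.29 for Nr1d1 (adjusted p = 0.681).

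These 3 genes (2 higher, 1 lower) were the total that changed between Abstinence and Saline by edgeR's quasi-likelihood test, and 707 genes had an unadjusted p under 0.05. In simulated counts, 79.1% of 2-fold and 35.8% of 1.5-fold changes were recovered in this comparison (15204 genes tested). The simulation changed 200 genes, all of mean log2 CPM of at least 2. These shares therefore do not cover lower genes or a comparison with few changes. In place of 3 genes, 15 changed without Maintenance 6, 7 and 8, 36 by DESeq2 and 56 in the 17 libraries that a second deposited table lists (46 higher, 10 lower). Among those 56 were 4 of the 16 oligodendrocyte markers, which vary together, and among the 176 genes that the same libraries gave for Maintenance were 10. Leaving out 1 library gave 1 gene without Saline 1, 2, 3, 5 or 6 or Abstinence 1, 2 or 6, 6 genes without Saline 7 or Maintenance 6, 7 genes without Abstinence 5 and 15 without Saline 8. Nr1d1 passed in every such fit. Hsph1 did not pass without Saline 1 (adjusted p = 0.0638), 2 (0.0617), 3 (0.0662), 5 (0.0582) or 6 (0.0631), or Abstinence 1 (0.0653), 2 (0.0844) or 6 (0.056). Dnaja1 did not pass without Saline 1 (0.0716), 2 (0.118), 3 (0.113), 4 (0.0616), 5 (0.078) or 6 (0.125), Maintenance 1 (0.0616), 2 (0.0579), 3 (0.058), 4 (0.0645), 5 (0.0649) or 7 (0.0545), or Abstinence 1 (0.155), 2 (0.196), 3 (0.13) or 6 (0.075). Hspa1a passed without Abstinence 4 (0.044) or 5 (0.00376), and Bag3 without Maintenance 6 (0.0326) or Abstinence 5 (0.0259).

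Abstinence was then compared with Maintenance, which asked what differed between the end of drug taking and the end of abstinence. Most chaperone genes of the list were lower in Abstinence. Hspa8 fell from 3472 ± 405 CPM in Maintenance to 1733 ± 262 CPM in Abstinence (it fell by 1.00 ± 0.09 on the log2 scale, adjusted p = 2.51e-07). Stip1, Ahsa2, Cacybp, Fkbp4 and Chordc1 also fell, with adjusted p from 1.72e-05 for Stip1 to 0.00564 for Fkbp4. The chaperone list was lower (median -0.32, camera adjusted p = 7.45e-13; adjusted p = 0.0251 with an estimated correlation). In it, 5 fell over all genes tested, and 9 fell and 3 rose when adjusted over the list alone. A positive fold change was found in 5 of the 19 members. Among them were Bag3 (0.68 ± 0.18, adjusted p = 0.0575), Hspa1b (0.84 ± 0.36, adjusted p = 0.362) and Hspa1a (0.59 ± 0.25, adjusted p = 0.37). Mthfd2 rose 3.44-fold, from 11.9 ± 2.58 to 40.8 ± 13.1 CPM (1.78 ± 0.20, adjusted p = 1.71e-05). Cirbp rose 2.56-fold to 83.4 ± 16.6 CPM (1.36 ± 0.16, adjusted p = 2.37e-05), and Etv5 rose 1.75-fold to 153 ± 20.7 CPM (0.81 ± 0.11, adjusted p = 0.00013). Ewsr1, Aars, Lars and Csf3r also rose, by 1.43-fold, 1.28-fold, 1.45-fold and 1.34-fold (adjusted p up to 0.00564), as did Cd180, a Toll-like receptor relative, by 1.57-fold (adjusted p = 0.000608). Lower genes included Glul, the glutamine synthetase (-0.52 ± 0.08, adjusted p = 0.000463), and Sult1a1, a sulfotransferase (-0.91 ± 0.11, adjusted p = 3.1e-05). Each gene named so far in this comparison, leaving aside Bag3, Hspa1a and Hspa1b, was beyond the Maintenance median in 7 of 7 Abstinence libraries.

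Clock genes and glucocorticoid-responsive genes also differed between Abstinence and Maintenance. Nr1d1 fell from 37.3 ± 11.3 CPM in Maintenance to 15.8 ± 4.88 CPM in Abstinence (-1.24 ± 0.21, adjusted p = 0.00196). Its paralog Nr1d2 fell from 99.3 ± 15.9 to 61.4 ± 11.7 CPM (-0.70 ± 0.14, adjusted p = 0.0113), and the period gene Per3 from 29.0 ± 6.86 to 13.5 ± 3.32 CPM (-1.10 ± 0.20, adjusted p = 0.00373), in 7 of 7 libraries each. Of the 21 clock genes, 4 fell over all genes tested, 11 fell and 1 rose when adjusted over the list alone, and the median log2 fold change was -0.45 (camera adjusted p = 1.26e-07; adjusted p = 0.0042 with an estimated correlation). The fourth, Tef, a clock output factor (-0.62 ± 0.15, adjusted p = 0.0463), did not pass without Saline 1 (0.0538) or 3 (0.0506), Maintenance 1 (0.0723), 6 (0.0674) or 7 (0.0662), or Abstinence 1 (0.0666), 2 (0.0769), 3 (0.0934), 4 (0.115), 6 (0.0994) or 7 (0.0514). Per1 measured 20.5 ± 4.1 CPM in Maintenance and 15.1 ± 3.34 CPM in Abstinence (-0.44 ± 0.17, adjusted p = 0.267), and 17.8 ± 3.56 CPM in Saline. The activator Arntl, singled out for its opposite phase after the fall of the clock genes was seen but before its own values were read, measured 7.25 CPM in Maintenance and 16.6 CPM in Abstinence (1.20 ± 0.55, adjusted p = 0.406), while its partner Clock had -0.15 ± 0.21 (adjusted p = 0.908). In Maintenance against Saline the clock list was higher (median 0.15, 15 of 21 positive, camera adjusted p = 0.0408; adjusted p = 0.254 with an estimated correlation). There 0 passed over all genes tested, and 2 rose and 1 fell when adjusted over the list alone. That call was lost without Saline 6 (0.0556), 7 (0.0722) or 8 (0.0847), or Maintenance 1 (0.0654), 6 (0.0691) or 7 (0.196). Glucocorticoid-responsive genes were lower in Abstinence (21 genes, median -0.30, camera adjusted p = 1.45e-06; adjusted p = 0.0326 with an estimated correlation), with 2 falling over all genes tested and 4 when adjusted over the list alone. Tsc22d3, the glucocorticoid-induced leucine zipper, fell from 864 ± 155 CPM in Maintenance to 591 ± 98.7 CPM (-0.55 ± 0.12, adjusted p = 0.0152). It had been higher in Maintenance than in Saline (598 ± 99.3 CPM, log2 fold change 0.53 ± 0.11, adjusted p = 0.02, or 0.0522 without Saline 3). That rise also did not pass with the replicate block or with the marker means as covariates. Fkbp5, a glucocorticoid receptor co-chaperone, measured 57.3 ± 13.6 CPM in Maintenance and 36.8 ± 7.09 CPM in Abstinence (-0.64 ± 0.19, adjusted p = 0.0978; adjusted p = 0.0171 without Saline 6). Lymphocyte markers averaged -0.95 ± 0.78 log2 CPM in Maintenance and 0.27 ± 0.61 in Abstinence (two-sided exact permutation p = 0.00684, adjusted p = 0.0656). Oligodendrocyte (6.87 and 6.96) and neutrophil means (0.71 and 0.46) differed by less than their SD. Means of other cells were higher in Abstinence than in Maintenance, by 1.60 for oligodendrocyte precursors (exact permutation p = 0.0288), 1.16 for neurons (exact permutation p = 0.0362), 1.03 for monocytes (exact permutation p = 0.0305) and 1.23 for erythrocytes (exact permutation p = 0.0297), with adjusted p of 0.146 to 0.15. Neuron markers were low in both (0.43 ± 1.20 in Maintenance, 1.59 ± 0.48 in Abstinence). Precursor means in Maintenance were -2.225 to -1.255 in replicates 3 and 5 to 8 and 1.11 to 1.376 in replicates 1, 2 and 4. The Abstinence mean was 0.87 ± 0.37, so the precursor difference rests on part of the Maintenance libraries, at low levels. Border macrophage markers were lower by 0.27 (exact permutation p = 0.0532, adjusted p = 0.15), and as a list (median -0.17, camera adjusted p = 0.00012; adjusted p = 0.249 with an estimated correlation; 0 passing over all genes tested and 2 falling adjusted over the list alone).

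Between Abstinence and Maintenance 153 genes changed by edgeR's quasi-likelihood test (64 higher, 89 lower), with 1769 at an unadjusted p under 0.05. Without Maintenance 6, 7 and 8 the count was 199, of which 96 were among the 153, and it was 265 without Maintenance 8, 89 without Abstinence 3, 92 without Abstinence 4 and 100 without Abstinence 7.

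**Figure D3:**
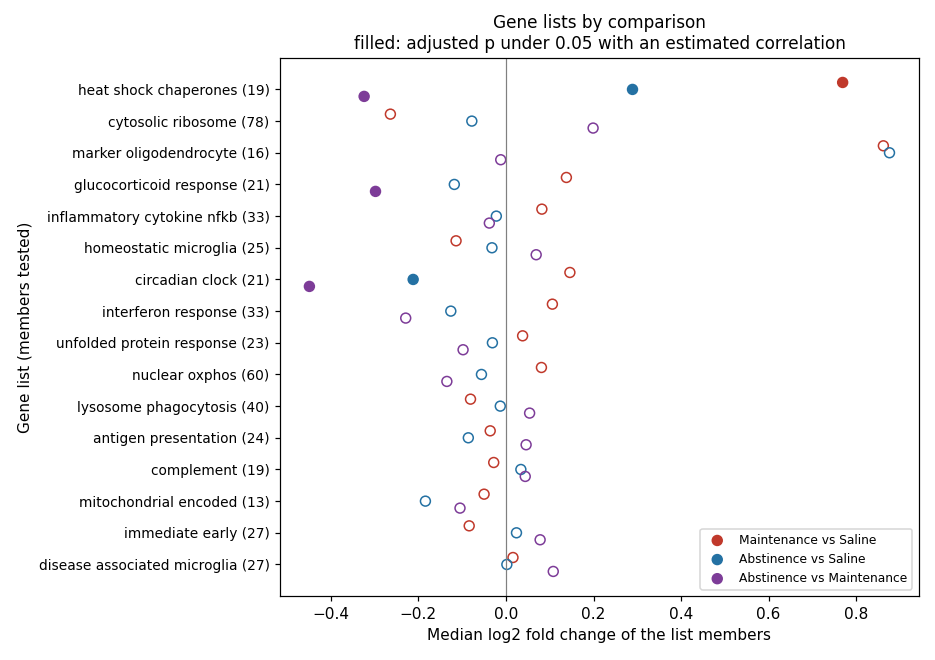
Median log2 fold change of 16 gene lists in the 3 comparisons (horizontal axis, points by comparison), with filled points for an adjusted p under 0.05 with an estimated correlation. Heat-shock chaperones had medians of 0.77 (Maintenance against Saline), 0.29 (Abstinence against Saline) and -0.32 (Abstinence against Maintenance), and clock genes had -0.45 in the last.

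Across the 3 stages, the genes that changed in Maintenance were followed into abstinence. Genes picked for high or low Maintenance values tend to move back by selection alone, so the direction was read in libraries that did not pick them, a check added after the values were seen. Genes called with 4 Maintenance libraries against Saline moved the opposite way between the other 4 and Abstinence in 80.1% of cases (median of 70 choices of 4 libraries, 63% to 100%), where no change gives about 50%. The choices reuse the same Saline and Abstinence libraries, and the genes move together, so this range is not an error range. Filter, scaling and spread were taken from all 23 libraries, and a feature shared by all Maintenance libraries would pass this check. For 60 of the 114 genes (26 higher, 34 lower in Maintenance) both changes passed their tests, among them Hspa8, Ahsa2, Stip1, Cacybp, Cirbp, Etv5, Mthfd2 and Ewsr1. Hsph1 and Dnaja1 passed in the same direction in Maintenance and in Abstinence against Saline, and Nr1d1 passed in Abstinence against both other groups. A single test over all 3 groups called 173 genes, and 193 without Maintenance 6, 7 and 8. It called 104 without Saline 1, 114 without Saline 2, 101 without Saline 3, 105 without Abstinence 2, 107 without Abstinence 3 or 4, 106 without Abstinence 6 and 108 without Abstinence 7. The 60 genes that moved back numbered 50 without Maintenance 6, 7 and 8 and 34 without Saline 3. The 2 that stayed changed numbered 0 without Saline 1, 2, 3, 5 or 6 or Abstinence 1, 2 or 6, 1 without Saline 4, Maintenance 1, 2, 3, 4, 5 or 7 or Abstinence 3, and 11 without Saline 8. The count of genes changed in Abstinence against both other groups went from 1 to 3 without Saline 7 and to 2 without Saline 8, Maintenance 6, Maintenance 8, Abstinence 3 or Abstinence 5. The log2 fold changes of Maintenance and Abstinence against the same Saline libraries correlated across 16121 genes, which are not independent replicates, at Pearson r = 0.462. Unchanged simulated groups that shared those libraries gave 0.474 (0.456 to 0.498 in 20 simulations). The covariance was 0.281 observed and 0.41 simulated, so the simulated fold changes spread more widely than the real ones. In 9893 genes of at least 2 mean log2 CPM the covariance was 0.09 observed and 0.039 simulated. The simulated r is therefore no exact match for the data. Across all 16121 genes, with different Saline libraries for each fold change, r was 0.187 (median of 35 splits, 0.14 to 0.225).

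**Figure D4:**
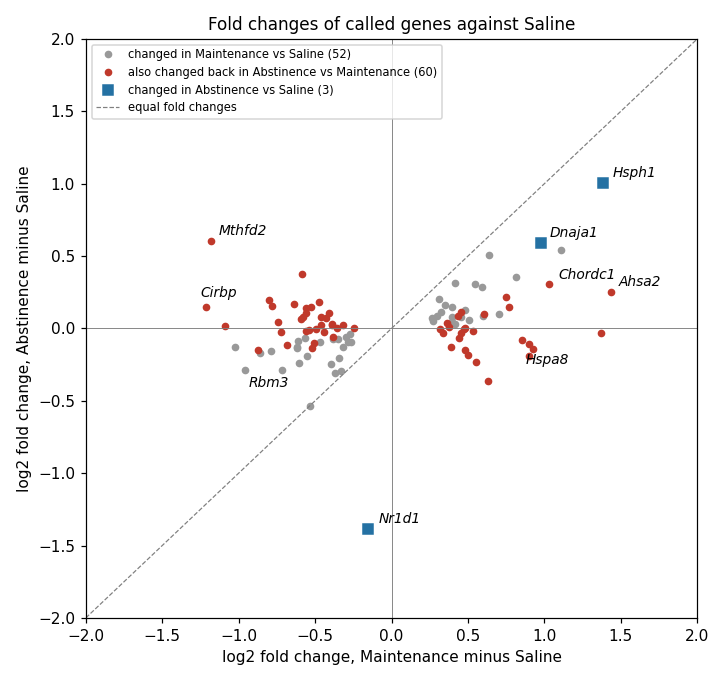
Log2 fold change against Saline in Maintenance (horizontal axis) and in Abstinence (vertical axis) for the 115 genes changed in either, each point 1 gene, with 8 genes outside the axes, which end at 2 in each direction. The 60 genes in red also changed back between Maintenance and Abstinence, the 52 in grey changed in Maintenance against Saline, and the 3 blue squares changed in Abstinence against Saline.

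Genes that define microglia and genes of inflammatory signalling, chosen in advance, were examined in all 3 comparisons. Of the single genes, Tmem119, P2ry12, Cx3cr1, Csf1r, Il1b, Tnf and Fos passed in none. The microglial genes Tmem119, P2ry12, Cx3cr1 and Csf1r measured 4210 ± 667, 9504 ± 958, 5245 ± 563 and 5445 ± 764 CPM in Saline, 3889 ± 484, 9818 ± 1214, 4704 ± 578 and 4749 ± 640 CPM in Maintenance, and 3782 ± 233, 9659 ± 871, 5348 ± 454 and 5532 ± 712 CPM in Abstinence. The smallest adjusted p among them was 0.34 (Cx3cr1, Abstinence against Maintenance). As a list, 25 homeostatic genes had a median of -0.11 in Maintenance (camera adjusted p = 0.0408; adjusted p = 0.709 with an estimated correlation; 0 passing over all genes tested or adjusted over the list alone). The call was lost without Saline 2 (adjusted p = 0.141), 3 (0.0765), 4 (0.0747) or 6 (0.2), or Maintenance 4 (0.0754), 6 (0.0542) or 8 (0.701). It was also lost with RLE factors (0.1), the stricter filter (0.0911) and the 17 libraries (0.407), and the direction turned without Maintenance 6, 7 and 8 (0.992). The cytokine genes Il1b and Tnf measured 51.4 ± 14.9 and 235 ± 55.2 CPM in Saline, 55.6 ± 10.5 and 214 ± 45.8 CPM in Maintenance, and 54.5 ± 8.52 and 204 ± 29.6 CPM in Abstinence, with adjusted p of 0.815 or more. The list of 33 inflammatory cytokine and NF-kB genes was higher in Maintenance than in Saline (median 0.08, camera adjusted p = 0.0233; adjusted p = 0.637 with an estimated correlation; 0 passing either way). It was lower in Abstinence than in Maintenance (median -0.04, adjusted p = 0.0346; adjusted p = 0.672 with an estimated correlation; 0 passing over all genes tested, 2 rising and 6 falling adjusted over the list alone). The former call was lost without Saline 3 (0.0845) or 8 (0.276), or Maintenance 2 (0.0529), 3 (0.0688), 5 (0.0601) or 7 (0.0972). The latter was lost without Maintenance 2 (0.0662), 3 (0.0755), 4 (0.0542), 5 (0.0775) or 7 (0.111), or Abstinence 6 (0.121). The immediate early gene Fos measured 4980 ± 584, 5119 ± 738 and 5221 ± 457 CPM in the 3 groups (adjusted p of 0.934 or more). Its level, like that of the immediate early list (median 826 CPM in Saline), was high in Saline already, so a rise could be hidden. Apoe, a lipid carrier induced in reactive microglia, rose from 1487 ± 212 CPM in Saline to 2075 ± 496 CPM in Maintenance (0.48 ± 0.11, adjusted p = 0.0456) and fell to 1344 ± 169 CPM in Abstinence (-0.63 ± 0.12, adjusted p = 0.00759). Of the 27 disease-associated microglial genes Apoe was the 1 that rose in Maintenance over all genes tested or adjusted over the list alone (camera adjusted p = 0.724). The rise of Apoe in Maintenance did not pass without Saline 1 (adjusted p = 0.0754), 2 (0.101), 3 (0.11), 4 (0.0975), 6 (0.0704) or 7 (0.0757), Maintenance 4 (0.0681), 6 (0.081) or 8 (0.0674), or Abstinence 1 (0.0519), 2 (0.0527), 3 (0.0596), 5 (0.0506) or 7 (0.0612). Its fold change was 0.28 without Maintenance 6, 7 and 8 (adjusted p = 0.203).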

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

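The tests of temperature, of cell isolation, of the 3 Maintenance libraries and of isolate purity were chosen after the results they bear on were seen, as was the p level asked of Arntl, while the direction of the clock genes and the split tests were set before.

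Chaperone genes rose in Maintenance (9 of 19, median log2 fold change 0.77) and 5 of the 19 fell from Maintenance to Abstinence. The heat-inducible Hspa1a and its co-chaperone Bag3 passed in neither group against Saline (0.77 and 0.16 in Maintenance, 1.35 and 0.84 in Abstinence). Nor did Hspa1b (0.78 and 1.62) or Dnajb1 (0.73 and 1.08). These genes are among the 5 of 19 with higher estimates in Abstinence than in Maintenance, a difference that passed for none of them (edgeR adjusted p = 0.0575 to 0.635). Their estimates therefore do not single out Maintenance, as heat at the end of drug taking would. Without Maintenance 6, 7 and 8, which hold few genes or choroid plexus RNA, 8 of the 9 called chaperones still passed, which argues against those libraries as the cause. A response to raised tissue temperature is a candidate explanation: the cold-inducible gene Rbm3 moved the other way (-0.72, adjusted p = 0.0047), as did Cirbp (-1.21), although both had been seen when the test was chosen and temperature was not measured. Hsph1 and Dnaja1 were also higher in Abstinence than in Saline (1.00 and 0.59). Both calls were lost without each of several single libraries, and with the marker covariates (edgeR adjusted p = 0.854 and 0.707). No Saline group passed through the 21 days, so these 2 genes cannot decide whether heat from the drug alone is enough. Stress of cell isolation stays open, since immediate early genes had a median of -0.084 (27 genes, 10 of them positive) but a median Saline level of 826 CPM that could hide a rise, and an effect of the drug without heat was not tested.

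Clock genes fell in Abstinence (Nr1d1 -1.24 and Per3 -1.10 against Maintenance). If the hour of isolation or the phase of the clock had differed, genes of opposite phase should move apart, and the activator Arntl was higher in Abstinence (1.20 ± 0.55). Arntl did not pass over all genes (adjusted p = 0.406), nor did Npas2, which is near the detection limit (1.93 ± 1.69, adjusted p = 0.807), and Clock had -0.15 ± 0.21, so the test leaves a shift of phase open, and the labels give no hour per library. Age, 21 days in the home cage and the end of daily sessions differ between the groups in the same way and were not tested. In Maintenance against Saline, collected at the same stage, the clock list was higher by camera (median 0.15, adjusted p = 0.0408; adjusted p = 0.254 with an estimated correlation; lost without Saline 6, 7 or 8 or Maintenance 1, 6 or 7, at 0.0556 to 0.196), so part of the fall of the list may lie in Maintenance. That does not hold for Nr1d1, which had -0.15 ± 0.19 in Maintenance against Saline (edgeR adjusted p = 0.87) and -1.39 ± 0.21 in Abstinence against Saline.

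Oligodendrocyte markers were higher and neutrophil markers lower in both methamphetamine groups by camera, but not with an estimated correlation (adjusted p = 0.207 and 0.254 in Maintenance, 0.16 and 0.146 in Abstinence). A general loss of purity would raise markers of every other cell type alike. In Maintenance against Saline the medians of neutrophil (-1.14), erythrocyte (-1.02) and monocyte markers (-0.78) were below 0 and that of oligodendrocyte markers above (0.86). Only 1 neutrophil gene, Csf3r, and 0 of the others passed singly (erythrocyte and monocyte lists, adjusted p = 0.267 each with an estimated correlation). The 12 lists together moved apart (exact permutation p = 0.00218). That test used marker means, and Maintenance libraries had fewer genes detected (14958.5 ± 1591 against 16279 ± 742 in Saline). The precursor mean, for example, differed by -0.44 while the fitted median was 0.22. The test therefore cannot tell a change of cells from lower library complexity, and draws no line on purity there. In Abstinence against Saline the same test gave exact permutation p = 0.0598, which leaves a general loss of purity open: oligodendrocyte (0.88), precursor (0.70), choroid plexus (0.69), neuron (0.32) and astrocyte markers (0.28) were higher, but neutrophil (-1.76), monocyte (-0.48), border macrophage (-0.08) and pericyte markers (-0.05) were lower. Fewer blood cells in the isolate could contribute in Maintenance, but in Abstinence erythrocyte and lymphocyte markers had medians of 0.01. More myelin debris was not tested, the labels describe no sort or gate, and Saline 6 weighs on the neutrophil result in Maintenance (adjusted p = 0.0574 without it).

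The count of 60 genes that changed in Maintenance and changed back by Abstinence is listed here because the difference between the stages passed its own test, although both tests used the same Maintenance libraries.

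Single libraries that lay far from the rest of their group were looked for in 186 groups of 7 or 8 values, of which 14 were beyond the critical gap of Dixon's test, where chance gives about 5%, or 1 in 20. Each is given with its gap as a share of the group's range. Abstinence 5 had 14727 genes detected, against 16277 to 16993 (0.684). Maintenance 5 had astrocyte markers at 3.44 log2 CPM, against 4 to 4.46 (0.541). Saline 6 had monocyte markers at 3.74, against 0.93 to 2.26 (0.53), and Fkbp5 at 6.96, against 5.42 to 5.97 (0.64). Maintenance 8 had choroid plexus markers at 6.27, against -3.23 to 0.29 (0.629), and Glul at 9.34, against 9.72 to 9.91 (0.671). Maintenance 6 had Eif4a2 at 8.45, against 8.15 to 8.29 (0.545), and Ptbp1 at 5.87, against 6.28 to 6.49 (0.675). Nubp1 in Maintenance 7 was at 3.35, against 4.41 to 4.82 (0.72), and Mthfd2 in Maintenance 4 at 2.74, against 3.44 to 3.90 (0.601). Cirbp in Abstinence 5 was at 5.67, against 6.25 to 6.63 (0.6). Csf2ra in Saline 8 was at 6.05, against 6.36 to 6.52 (0.668), Eya4 in Saline 7 at 5.69, against 4.91 to 5.24 (0.579), and Peg13 in Saline 4 at 5.48, against 5.12 to 5.25 (0.649).

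Other splits of the same libraries into groups of the same sizes were tried, 100 per result with the real one included. Only the real split reached its count for Maintenance against Saline (1 of 100 splits with as many genes, 114 in the real split and 2 at the highest other). The same held for Abstinence against Maintenance (1 of 100, 153 and 5) and for the 3 groups together (1 of 100, 173 and 0). A share of 1 of 100 is the smallest that these splits can give, so chance is unlikely for these counts within that limit. For Abstinence against Saline 2 of 100 splits gave 3 genes or more, a share under the limit set in advance. The highest other split gave 25, with Saline 1, 2, 3, 4, 6 and 7 and Abstinence 4 together, so chance is not excluded for these 3 genes. That split follows the groups but for Saline 5, Saline 8 and Abstinence 4, and a count several times the real one points to a structure of the samples, which was not tested further.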

How the results depend on the processing

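The 17-library, reduced-Maintenance and marker-covariate settings were chosen only after the result was seen; the others were planned. Among named genes, 84 called results were kept 1150 times and lost 110 times with other settings, and kept 1797 times and lost 135 times without 1 library, and 0 reversed. Results not called in the main fit were gained 37 times with other settings and 8 times without 1 library. One of them was Hspa1a in Abstinence against Saline (adjusted p = 5.26e-05 by DESeq2 and 0.0058 by limma voom). Counts not given stayed within 1.5 times their value. Where a cause is not stated, the cause was not tested.

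In the order Maintenance against Saline, Abstinence against Saline, Abstinence against Maintenance and 3 groups together (114, 3, 153 and 173 genes), DESeq2 gave 351, 36, 471 and 526, limma voom 411, 184, 331 and 858, the 17 libraries 176, 56, 238 and 295, and the 17 libraries with DESeq2 444, 229, 566 and 721. For the first 3, only the compared groups gave 57, 5 and 64. The stricter filter, which tests fewer genes, gave 6 and 242 for the 2 Abstinence comparisons, and 1 surrogate variable gave 311 for the last. Marker covariates gave 40 for Maintenance and 0 for Abstinence against Saline (Hsph1 1.00 ± 0.17 became 0.97 ± 0.23, so the call ended with a wider error and not with a smaller estimate). For Abstinence against Saline, leaving out Maintenance 6 and 7 gave 6 and 6, 7 and 8 gave 15. Without 1 library the counts ranged from 42 to 197, 1 to 15, 89 to 265 and 101 to 227.

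Replicate numbers do not pair the libraries: 22 pairs of the same number correlated at -0.007 on average (-0.225 to 0.195). The replicate block therefore serves only as an alternative here, and gave 69 genes for Maintenance against Saline, 1 that stayed changed and 2 that changed in Abstinence against both groups, and it turned the nuclear respiratory chain list in Abstinence against Saline (adjusted p = 0.957).

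Genes that stayed changed (2) numbered 1 with upper-quartile factors, 9 with DESeq2, 37 with voom, 35 in the 17 libraries, 115 there with DESeq2 and 0 with covariates (0 to 11 without 1 library). Genes changed in Abstinence against both groups (1) numbered 2 with the stricter filter, 12 with DESeq2, 36 with voom, 7 in the 17 libraries, 38 there with DESeq2, 2 and 6 without Maintenance 6 and 7 or 6 to 8, and 0 with covariates (1 to 3 without 1 library). Genes that moved back (60) numbered 169 with DESeq2, 152 with voom, 113 with a surrogate variable, 181 in the 17 libraries with DESeq2 and 26 with covariates (34 to 84 without 1 library).

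Lists that passed (20, 15 and 13 in the 3 comparisons) numbered 1, 2 and 3 with an estimated correlation and 4, 2 and 4 with fry. For Maintenance against Saline they numbered 12 with the stricter filter, 11 in the 17 libraries and 13 without Maintenance 6 to 8, and for Abstinence against Maintenance 6 in each of the latter settings. Without 1 library they ranged from 13 to 20, 10 to 17 and 8 to 17. Homeostatic genes in Maintenance turned without Maintenance 6 to 8 (adjusted p = 0.992), endothelial markers turned there (adjusted p = 0.14) and in the 17 libraries (0.53), and the nuclear respiratory chain list in Abstinence against Maintenance turned without Maintenance 8 (0.14) and had 2.41e-06 without Maintenance 7. The correlation of fold changes (0.462) was 0.187 with separate Saline libraries, where no library is shared, and 0.517 in genes of at least 2 mean log2 CPM, where unchanged simulated groups gave 0.461 (0.381 to 0.54) and separate Saline libraries 0.381.

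Not run were the omission of shallow libraries, since 0 libraries were that far below the median total, and the authors' size factors, since the second table holds unscaled counts.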

Other observations

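The tests of the ATF4, splicing and ERK hypotheses were written after the genes that raised them were seen but before the values of their lists were, and the gene groups that open this part were chosen after the result was seen.

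Other gene groups also differed by list, and none of those in this paragraph passed with an estimated correlation. Mitochondrially encoded respiratory chain genes were lower in Abstinence than in Saline (13 genes, median log2 fold change -0.18, camera adjusted p = 0.00121; adjusted p = 0.789 with an estimated correlation). Of them 0 passed over all genes tested or adjusted over the list alone, the list had adjusted p = 0.0536 without Saline 7, and COX1 was at 1658 ± 285 and 1446 ± 193 CPM. Cholesterol synthesis genes were higher (24 genes, median 0.17, 0 passing either way, adjusted p = 0.00541; adjusted p = 0.875 with an estimated correlation), with the desaturase gene Scd2 at 93.7 ± 25.3 and 149 ± 36.9 CPM (adjusted p = 0.546). Markers of oligodendrocyte precursors were higher in Abstinence than in Saline (12 genes, median 0.70, 0 passing either way, adjusted p = 0.0026; adjusted p = 0.48 with an estimated correlation), with Olig1 at 9.33 ± 9.05 and 24.0 ± 10.6 CPM (adjusted p = 0.678).

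Interferon-responsive genes were lower in Abstinence than in Maintenance (33 genes, median -0.23, camera adjusted p = 6.14e-05; adjusted p = 0.396 with an estimated correlation), where Ifit3, an antiviral effector, fell over all genes tested and 2 fell when adjusted over the list alone. Ifit3 fell from 31.8 ± 19.0 to 16.1 ± 4.57 CPM (-0.98 ± 0.24, adjusted p = 0.0447), and did not pass without Saline 1 (0.0538), 2 (0.056), 3 (0.0522) or 4 (0.0524), Maintenance 6 (0.0611) or 7 (0.0666), or Abstinence 2 (0.08), 3 (0.0825), 4 (0.115), 5 (0.0533), 6 (0.0994) or 7 (0.0887). Its log2 fold change was -0.51 without Maintenance 6 and 7 (adjusted p = 0.116) and -0.55 in the 17 libraries (adjusted p = 0.0895). Vasp, which extends actin filaments, rose in the same comparison from 37.4 ± 9.07 to 66.1 ± 17.8 CPM (0.82 ± 0.17, adjusted p = 0.0127).

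A lower amino acid stress (ATF4) programme is a candidate explanation for the fall of Mthfd2, Phgdh and Aars in Maintenance. A list of 32 further ATF4 targets, without those genes, had a median log2 fold change of -0.186, with 22 negative and with Mars, Aldh18a1 and Shmt2 falling over all genes tested (limma's fry adjusted p = 0.00077 over 4 lists; camera adjusted p = 0.0596 with an estimated correlation). In Abstinence against Maintenance the median was 0.195 (fry adjusted p = 0.00021; camera adjusted p = 0.039). The direction was the one the hypothesis needs, in a list that could have come out the other way, but it did not pass every test and ATF4 protein was not measured.

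RNA-binding protein genes such as Srsf5 and Ptbp1 fell in Maintenance, and a broad fall of splicing regulators was put as a hypothesis. A list of 46 further splicing regulators had a median of 0.146 (fry adjusted p = 0.0077, camera adjusted p = 0.0336 with an estimated correlation), and 5 rose and 1 fell. This argues against a broad fall, although the list left out the called genes that raised the question.

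Lower ERK pathway output could account for the fall of Etv5. The 15 further ERK feedback genes had a median of -0.134 in Maintenance (fry adjusted p = 0.105, 10 negative, 0 passing over all genes tested), so the test leaves this open. For the fall of Csf2ra and Csf3r, 11 further cytokine receptor genes had a median of -0.044 (fry adjusted p = 0.125), and no outcome had been named for them.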
